A study of Mus musculus with 9 samples.

How the data were processed

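Poly-A RNA of the caput epididymis of 14-week-old mice was sequenced in 9 libraries, 3 each of WT, EDL and W/Wv, from stranded mRNA libraries per the labels' protocols, on a NovaSeq6000 per the series' design text. Groups and replicate numbers were taken from the sample titles. TopHat2 2.1.1, Cufflinks 2.2.1 and the mm10 build are named per the submitters' processing notes, with no role or order. The annotation, the filters, whether counting used the strand, and how the 2462 genes of the table were chosen are not given in the sources used here.

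The authors deposited 1 table with a normalized FPKM per gene and library, per the file headers; how FPKM was normalized between libraries is not given in the sources used here. The authors also deposited a normalized count per gene and library, a signal that is a read count divided by 1 factor per library, as the low values show. Whole reads were recovered from it: with a tolerance of 0.1 of a read, 98.8% to 99.0% of all values in a library came out whole. The factors ranged from 0.922 to 1.25, and the libraries had 3536247 to 4793224 reads in the table. A read was worth a median of 0.0161 to 0.0222 FPKM. Gene symbols and identifiers are those of the table, and 2454 of 2462 identifiers matched an NCBI gene table of the GRCm38.p6 assembly, the build that mm10 names, from which coordinates were taken. No 2 libraries of a group were alike within sampling noise (chi-square per gene 3.25 to 24.9), and each counted as 1 replicate.

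The main test was limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes step, on log2(FPKM + 1) with a pseudocount of 1. Genes with an FPKM of 1 or more in at least 3 libraries entered, which left 2013. All 9 libraries entered 1 fit, so that the groups share an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Changes are on the log2(FPKM + 1) scale, which understates those of low genes. Since the deposited unit is FPKM, this test and not a count model is the main one. After the data were seen, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as added alternatives; they called 1534 and 1490 genes in EDL against WT. For genes whose reads are all 0 in a group, a floor of 3 reads over the group gives a lower bound of the fold.

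The lists, 18 of genes and 16 of cell type markers, were fixed before the data were examined, and the 13 lists with 3 or more members tested entered camera with a correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Many lists had few members in the table. The rule for named genes, fixed at the same time, took Kit first, the 10 genes that rose and the 10 that fell most among those past the threshold with at least 5 FPKM in the higher group and no overlap between groups, and up to 4 members of each list described. Kit was not analysed here. The alternatives were another pseudocount, no filter and a stricter one, median-ratio and quantile scaling, a fit of only the groups compared, a block of replicate numbers, a plain empirical Bayes step and leaving out each library.

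The tests were tried on simulated data, with reads drawn from the WT means and the factors of the libraries. For the comparison of EDL with WT, with 1960 genes tested and 50 genes changed at each size, limma recovered 24% of genes changed 1.25-fold, 88% of those changed 1.5-fold and 100% of those changed 2-fold, with 8 calls among 1760 unchanged genes. GC content and length were taken from the longest GENCODE transcript of a symbol. Plots were drawn with matplotlib 3.10.9.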

Results

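Messenger RNA was profiled in the caput epididymis, the first part of the duct in which sperm mature, of 14-week-old mice. The 9 libraries form 3 groups of 3: wild-type mice (WT), mice whose efferent ducts had been ligated (EDL), which stops fluid and sperm of the testis from reaching the epididymis, and mice of the W/Wv genotype, which carry mutant alleles of Kit and have testes almost without germ cells. The deposited table lists 2462 genes with an FPKM and a normalized count per gene and library. The reads recovered from it number 3536247 to 4793224 per library, and its 5 most abundant genes take 29.3% to 33.5% of them. The table is a part of the transcriptome and is rich in genes that differ between the groups, so shares of changed genes below describe this table and not the genome. The labels do not say that the 3 libraries of a group come from separate animals, and p-values measure the spread between these libraries.

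Kit itself was not analysed here. Of the mast cell markers, a cell type that depends on Kit, 3 could be read from the table at low depth, Cpa3, Cma1 and Mcpt4. Together they had 32 reads in the 3 WT libraries, 42 in the 3 EDL libraries and 0 in the 3 W/Wv libraries. Against a floor of 3 reads over the group, the W/Wv level was at least 10.1-fold lower than that of WT and at least 12.1-fold lower than that of EDL, a bound that covers counting error only.

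The comparison of EDL with WT asked what the caput expresses when fluid and sperm of the testis do not reach it. The sample titles name no sham operation for WT or W/Wv. Effects of the operation itself therefore cannot be told from those of the block in any comparison with EDL. The largest fall on the log2(FPKM + 1) scale was that of Lcn8. This gene, a lipocalin (chromosome 2, 25653118 to 25656217, mm10), went from 17981 ± 2689 FPKM in WT to 3.66 ± 0.947 in EDL (SD, n = 3 each), a change of -11.92 on the log2(FPKM + 1) scale (SE 0.15, limma with Benjamini-Hochberg adjusted p = 6.4e-12). Cst8, a cystatin-related protein (chromosome 2, 148798839 to 148805596), went from 2557 ± 335 to 1.11 ± 0.249 FPKM (adjusted p = 1.2e-13). Crisp1, a secreted protein that binds sperm (chromosome 17, 40293758 to 40319207), went from 1498 ± 164 to 1.78 ± 0.128 FPKM, and Ovch2, a secreted protease (chromosome 7, 107781544 to 107801179), from 1143 ± 119 to 22.8 ± 0.394 FPKM. Other genes rose, led by Lcn5, a lipocalin that binds retinoids (chromosome 2, 25657932 to 25662230), from 702 ± 791 to 9752 ± 169 FPKM (log2 change 4.43, SE 0.76, adjusted p = 0.0016).

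The remaining genes with the largest falls in EDL on the log2(FPKM + 1) scale, which understates those of low genes, were 9230104L09Rik, Dapl1, Erdr1, Shc4, Cst12 and 9230102K24Rik. The transcript 9230104L09Rik, which lies beside Cst8 and Cst12 on chromosome 2, went from 9611 ± 1152 to 6.42 ± 2.93 FPKM. Dapl1 fell from 109 ± 14.2 to 0.248 ± 0.12 FPKM, and Shc4, an adaptor of receptor tyrosine kinases, from 45.7 ± 4.43 to 0.201 ± 0.0508 FPKM. Cst12 fell from 6007 ± 771 to 183 ± 19 FPKM. The transcript 9230102K24Rik had 2044 reads in the WT libraries and 0 in EDL, at least 747-fold lower against a floor of 3 reads over the group. Ntsr1, a neurotensin receptor that this scale ranks lower, had 6250 reads in WT and 0 in both models, at least 2284-fold lower in EDL. Erdr1 varied widely among the WT libraries, at 5.34, 153 and 97.2 FPKM, against 0.155 ± 0.126 in EDL (adjusted p = 0.0077).

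Among the genes that rose were 3 antimicrobial peptide genes on chromosome 8. Spag11a rose from 143 ± 17.7 to 828 ± 9.57 FPKM (log2 change 2.53, SE 0.10, adjusted p = 1.9e-09), Defb35 from 11.7 ± 7.8 to 70.5 ± 6.63 and Defb15 from 421 ± 395 to 1933 ± 140. S1pr3, a receptor for sphingosine 1-phosphate, rose from 3.46 ± 2.14 to 20.6 ± 0.802 FPKM, the proteoglycan Gpc2 from 1.71 ± 0.254 to 12.4 ± 0.699, and Dysf, a protein of membrane repair, from 5.77 ± 1.46 to 31.4 ± 1.58. Gm4926 rose from 1.33 ± 0.858 to 18.5 ± 0.573 and Pisd-ps1 from 12.3 ± 2.17 to 64.2 ± 1.13 FPKM. The WT values of Lcn5 and Defb15 rested partly on library 3, which had 1613 FPKM of Lcn5 against 308 and 186 in libraries 1 and 2, and 872 FPKM of Defb15 against 252 and 138. Without WT library 3, the log2 change was 5.34 for Lcn5, EDL versus WT, and 3.37 for Defb15, EDL versus WT.

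**Figure D1:**
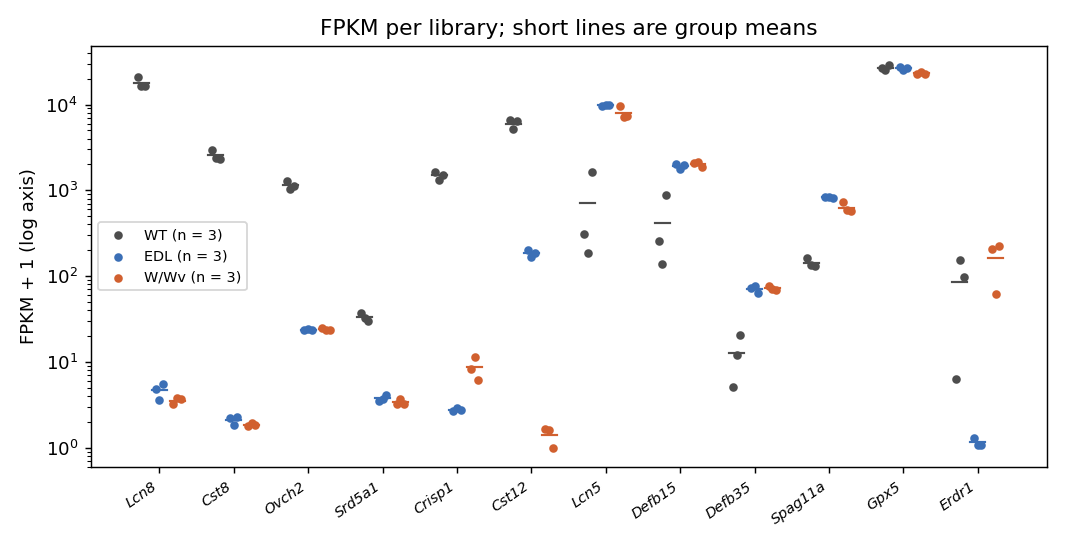
FPKM + 1 on a log axis for 12 genes in each of the 9 libraries; points are libraries, short lines are the means of the 3 libraries of a group (WT grey, EDL blue, W/Wv orange). Lcn8 and Cst8 lie far below WT in both models, and Cst12 keeps 183 FPKM in EDL and 0.415 in W/Wv. Lcn5 is higher in both models, with WT library 3 above the other WT libraries.

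In all, 1516 of the 2013 genes tested changed between EDL and WT, of which 793 rose and 723 fell. At 2-fold or more, 143 rose and 225 fell, and 37 of the falls but 2 of the rises reached 8-fold. The values of the groups did not overlap in 77.4% of the genes, against 10% by chance. Genes of each group were then counted over lists fixed before the data were examined. Of the list of initial segment and lumicrine-dependent genes, 8 of its 20 genes were tested, and 6 fell and 2 did not pass the test (6 changed when adjusted over the list alone). Its members included Lcn8, Cst8, Ovch2, Cst12 and Srd5a1, a steroid 5-alpha-reductase, which fell from 32.4 ± 3.78 to 2.76 ± 0.347 FPKM. The list was lower than other genes by camera (adjusted p = 0.0008), a call lost with an estimated correlation (adjusted p = 0.20 with an estimated correlation). Gpx5, a secreted glutathione peroxidase on the same list, had 26828 ± 1869 FPKM in WT and 26326 ± 1203 in EDL (adjusted p = 0.79).

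Markers of testicular germ cells and sperm were also lower: of 10 members tested all 10 fell (10 adjusted over the list alone). The camera adjusted p was 6.5e-05, and 0.040 with an estimated correlation. Whether their reads in WT came from sperm in the lumen or from the caput itself was not tested. The protamine gene Prm2 went from 14.3 ± 1.28 to 0.042 ± 0.0728 FPKM, Prm1 from 10.1 ± 1.74 to 0.0727 ± 0.126, and Dkkl1 from 81.9 ± 5.29 to 1.79 ± 0.278. Smcp, a protein of the sperm mitochondrial capsule, had 323 reads in WT and 0 in EDL, at least 118-fold lower. The smallest change was that of Odf2, from 16.5 ± 0.407 to 13.4 ± 0.309 FPKM. All 6 cholesterol synthesis genes tested fell (6 adjusted over the list alone; camera adjusted p = 0.0024; adjusted p = 0.20 with an estimated correlation), among them Dhcr7, from 10.3 ± 1.07 to 0.802 ± 0.0353 FPKM, and Lss, from 24.2 ± 2.53 to 7.16 ± 0.495. All 5 secreted and membrane proteases tested fell (5 adjusted over the list alone; camera adjusted p = 0.0057; adjusted p = 0.12 with an estimated correlation), including the proprotein convertase Pcsk5, from 56 ± 5.09 to 6.12 ± 0.18 FPKM, and the matrix metalloproteinase Mmp7, from 154 ± 14.6 to 33.9 ± 3.89.

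The other lists with at least 3 members tested did not pass in EDL. Of 7 beta-defensin genes 5 rose and 2 did not pass (5 changed when adjusted over the list alone; camera adjusted p = 0.094), with Defb45 at 511 ± 207 FPKM in WT and 1368 ± 153 in EDL. Of 8 protease inhibitors 2 rose, 5 fell and 1 did not pass (7 adjusted over the list alone, camera adjusted p = 0.084). Of 7 principal cell markers 1 rose, 4 fell and 2 did not pass (5 adjusted over the list alone, camera adjusted p = 0.073). Of 4 lipocalins 2 rose and 2 fell (4 adjusted over the list alone, camera adjusted p = 0.71). Glutathione metabolism and peroxidases had 2 genes that rose, 1 that fell and 1 that did not pass (3 adjusted over the list alone, camera adjusted p = 0.82). Androgen response and steroid metabolism had 1, 2 and 1 (3 adjusted over the list alone, camera adjusted p = 0.65). In the same order, ion and water transport had 3, 2 and 0 (5 adjusted over the list alone, camera adjusted p = 0.82), the interferon response 2, 0 and 2 (2 adjusted over the list alone, camera adjusted p = 0.51) and apoptosis 1, 1 and 2 (2 adjusted over the list alone, camera adjusted p = 0.82). Single markers of other cell types changed too. Uchl1, listed for nerve, fell from 45.6 ± 2.72 FPKM to 5.57 ± 0.041 in EDL and 7.08 ± 0.249 in W/Wv. Plin4, listed for adipocytes, rose from 6.45 ± 0.701 to 13.4 ± 0.877 and 11.8 ± 1.29.

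The comparison of W/Wv with WT asked what the caput expresses when the ducts are open but the testis is almost without germ cells. Lcn8, Cst12 and Cst8 led the falls. Lcn8 went from 17981 ± 2689 FPKM in WT to 2.55 ± 0.293 in W/Wv (log2 change -12.30, SE 0.15, limma adjusted p = 6.6e-12), Cst8 to 0.846 ± 0.0793, Crisp1 to 7.68 ± 2.67 and Ovch2 to 22.9 ± 0.857. Cst12 went from 6007 ± 771 to 0.415 ± 0.36 FPKM. St6galnac2, a sialyltransferase, fell from 166 ± 24.6 to 3.85 ± 0.637 FPKM, and 9230104L09Rik, Dapl1, Shc4 and 9230102K24Rik were again among the 10 largest falls. Lcn5 again led the genes that rose, to 8035 ± 1270 FPKM (log2 change 4.14, SE 0.76, adjusted p = 0.0025), followed by S1pr3 at 30 ± 1.28, Defb35 at 70.8 ± 3.96 and Defb15 at 2026 ± 158.

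Further genes that rose in W/Wv were Snhg11, a noncoding host transcript of small nucleolar RNA, from 0.705 ± 0.125 to 8.07 ± 0.654 FPKM, the microtubule protein Map1b, from 14.4 ± 2.26 to 75 ± 1.03, Tmc5, from 2.73 ± 0.816 to 17.3 ± 1.62, the chloride channel Ttyh3, from 13.5 ± 1.82 to 68.3 ± 7.94, the proteoglycan Spock1, from 11.5 ± 2.13 to 58.1 ± 2.38, and Dysf, to 33.9 ± 2.32. In all, 1416 of 2013 genes changed, of which 711 rose and 705 fell. At 2-fold or more, 132 rose and 207 fell. The groups did not overlap in 71.9% of the genes, against 10% by chance.

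All 8 initial segment genes tested fell in W/Wv (8 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.16 with an estimated correlation). Of these, Gpx5 differed little, at 23125 ± 795 FPKM against 26828 ± 1869 (adjusted p = 0.040), and its call was lost under 8 of the alternatives. All 10 germ cell and sperm genes fell (10 adjusted over the list alone; camera adjusted p = 3.3e-05; adjusted p = 0.034 with an estimated correlation), all 6 cholesterol synthesis genes fell (6 adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.23 with an estimated correlation), and all 5 proteases fell (5 adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.097 with an estimated correlation). Dkkl1 was at 2.04 ± 0.383 FPKM, Dhcr7 at 1.1 ± 0.331, Lss at 7.01 ± 0.342, Pcsk5 at 6.55 ± 0.299 and Mmp7 at 52.1 ± 10. Of 8 protease inhibitors 6 fell, 1 rose and 1 did not pass (7 changed when adjusted over the list alone; camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation), among them Wfdc2, from 29.9 ± 4.4 to 4.48 ± 0.216 FPKM. Of 7 principal cell markers 5 fell, 1, Krt8, did not pass and 1, Lcn5, rose (6 changed when adjusted over the list alone). This list passed camera (adjusted p = 0.045), but not with an estimated correlation (adjusted p = 0.31). Krt8 had 214 ± 11.4 FPKM in W/Wv against 207 ± 3.15 in WT. The lists overlap, so their calls are not separate results. Lcn8, Cst8, Crisp4 and Gpx5 are also on the initial segment list, as are the inhibitor Cst12 and the protease Ovch2. Of 7 beta-defensin genes 5 rose, 1, Spag11b, fell and 1 did not pass (6 adjusted over the list alone, camera adjusted p = 0.064). Lipocalins had 2 genes that rose, 2 that fell and 0 that did not pass (4 adjusted over the list alone, camera adjusted p = 0.76). In the same order, glutathione metabolism and peroxidases had 1, 2 and 1 (3 adjusted over the list alone, camera adjusted p = 0.90) and androgen response and steroid metabolism 2, 2 and 0 (4 adjusted over the list alone, camera adjusted p = 0.76). Ion and water transport had 3, 2 and 0 (5 adjusted over the list alone, camera adjusted p = 0.84), the interferon response 2, 0 and 2 (2 adjusted over the list alone, camera adjusted p = 0.56) and apoptosis 1, 1 and 2 (2 adjusted over the list alone, camera adjusted p = 0.90).

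Both sets of changes were then set side by side. Of the genes tested, 658 rose and 650 fell in both models, where independent lists would share 280 and 253. Of the 304 genes that changed 2-fold or more in the same direction in both, 196 fell and 108 rose. Across genes, which are not independent replicates, the log2 changes had Pearson's r of 0.95 and Spearman's rho of 0.95, and 90.2% had the same sign. Both comparisons use the same WT libraries. In 100 simulations of unchanged groups against shared controls r averaged 0.49, with a highest value of 0.73, and 66.5% of signs were the same. The covariance was 1.05, against 0.0064 in the simulations. The simulations drew genes independently, with 1 spread per gene for all 9 libraries. In the data the WT libraries vary more than the others (chi-square per gene 16.3 to 24.9, against 3.25 to 8.02). A larger spread of shared controls, or genes that move together, can raise such values. The simulated ones may therefore be too low. Only 6 genes passed the test in opposite directions, Gm7120, Lrrc10b, AA465934, Slc16a11, Myh10 and Ephb2, which were named for that reason after their values were seen.

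**Figure D2:**
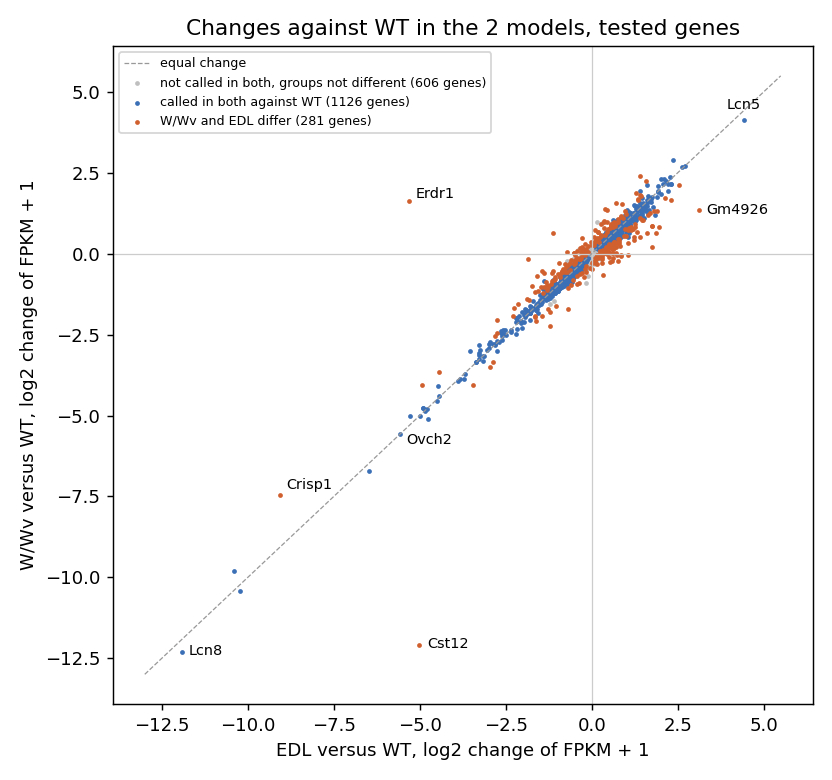
Log2 change of FPKM + 1 against WT in EDL (horizontal) and in W/Wv (vertical) for the 2013 genes tested, 1 point per gene, with a dashed line of equal change. Most points follow the line, 281 genes (orange) differ between the models by the limma test, and Cst12, Erdr1 and Crisp1 lie apart from it.

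The direct comparison of W/Wv with EDL asked where the 2 models differ. Of 2013 genes, 281 differed, 140 higher and 141 lower in W/Wv, and 12 of them by 2-fold or more (36 with a pseudocount of 0.1, 41 with edgeR and 39 with DESeq2). Cst12 was lower in W/Wv in every library, at 0.644, 0.602 and 0 FPKM against 202, 164 and 183 in EDL (log2 change -7.05, SE 0.19, limma adjusted p = 1.3e-07). Crisp1, far below its WT level in both, was higher in W/Wv, at 7.68 FPKM against 1.78 in EDL (log2 change 1.60, SE 0.20, limma adjusted p = 0.0014). Erdr1 was higher in W/Wv, at 206, 60.7 and 224 FPKM (log2 change 6.95, adjusted p = 0.016), but its adjusted p ranged up to 0.061 over the alternatives. Fos, an immediate early gene, had 5.18 ± 1.52 FPKM in W/Wv and 0.859 ± 0.117 in EDL, and Gm7120 had 27.4 ± 3.99 and 7.42 ± 1.67.

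Other genes were higher in W/Wv than in EDL. Snhg11 had 8.07 ± 0.654 against 3.54 ± 0.0857 FPKM, the lysosomal channel Mcoln3 15.2 ± 0.79 against 7.15 ± 0.405, Gsto1 25.6 ± 0.282 against 13.4 ± 2.2, the tight junction protein Cldn10 12.4 ± 3.16 against 6.17 ± 0.686, Plxdc1 19.9 ± 1.04 against 10.5 ± 0.722 and Ano10 24.7 ± 0.726 against 13.7 ± 0.608. Lower in W/Wv were Gm4926, at 4.66 ± 0.536 against 18.5 ± 0.573 FPKM, the lysosomal peptidase Dpp7, at 3.82 ± 0.806 against 12.8 ± 0.565, the phospholipase Plb1, at 2.68 ± 0.487 against 6.9 ± 1, the fibrinogen chain Fga, at 4.98 ± 0.546 against 11.1 ± 0.6, and the kinase subunit Camk2b, at 11.2 ± 0.729 against 23.6 ± 0.894. Lrrc10b, H2-Q4, Zfp950 and Gm1673 were lower too, with log2 changes of -0.997, -0.91, -0.90 and -0.83.

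Of 8 protease inhibitors 4 were lower in W/Wv than in EDL and 4 did not pass (4 adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.64 with an estimated correlation). These were Cst12, Wfdc10, at 2862 ± 54.1 against 3813 ± 363 FPKM, Spint2, at 645 ± 38 against 838 ± 43.9, and Spink10, at 77.8 ± 11.2 against 102 ± 2.45. Of the initial segment genes 1, Cst12, was lower and 7 did not pass (1 adjusted over the list alone; camera adjusted p = 0.037; adjusted p = 0.64 with an estimated correlation). None of the 10 germ cell and sperm genes differed by limma (0 adjusted over the list alone, camera adjusted p = 0.96). Of 6 cholesterol synthesis genes Nsdhl and Sc5d were higher in W/Wv and 4 did not pass (2 adjusted over the list alone, camera adjusted p = 0.13). The genes higher, lower and not passed were 1, 0 and 3 for androgen response and steroid metabolism (1 adjusted over the list alone, camera adjusted p = 0.30), 1, 0 and 4 for ion and water transport (3 adjusted over the list alone, camera adjusted p = 0.79) and 1, 1 and 2 for glutathione metabolism and peroxidases (2 adjusted over the list alone, camera adjusted p = 0.92). They were 0, 0 and 4 for lipocalins and for the interferon response (0 adjusted over the list alone for each), 0, 1 and 6 for beta-defensins (1), 1, 1 and 3 for proteases (2), 1, 1 and 2 for apoptosis (2) and 1, 0 and 6 for principal cells (1), with a camera adjusted p of 0.96 for each of these lists. The count of 281 fell to 174 without EDL library 1 or 3, to 187 without EDL library 2 and to 181 without W/Wv library 1. It rose to 385 without WT library 3 and to 425 in a fit of only these 2 groups. How reads shared by related genes were assigned is not stated, so single values of the cystatin genes of chromosome 2 and the defensin genes of chromosome 8 are uncertain.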

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

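The tests of WT library 3, of Cst12 and of scaling in the RNA-binding genes, and the read limits for low genes, were chosen after the results, Car6 and Sycp1 included, were seen; the tests of GC content with length and of depth in the RNA-binding genes were written before. Groups of 3 are too small for a test of outlying libraries. Intervals in this part come from resampling genes, which are not independent replicates, and leave out the spread between libraries.

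The effect in W/Wv differed from that in EDL, by the limma test of the difference itself, in the 34 genes below. They come from the largest rises and falls named by rule, the lists past the camera threshold and the genes of opposite direction. Outside these sets, other list members and markers differed too, by log2 W/Wv minus EDL: Uchl1 (0.30), Cftr (0.31), Gsr (0.20), Casp9 (0.18), Pmaip1 (-0.48) and Gpx8 (-0.41). In log2 units, W/Wv minus EDL, the 6 genes that changed in opposite directions against WT differed by 1.76 (Gm7120), -0.997 (Lrrc10b), -0.81 (AA465934), -0.58 (Slc16a11), 0.53 (Myh10) and 0.48 (Ephb2). Higher in W/Wv were Erdr1 (6.95), Fos (1.70), Crisp1 (1.60), Snhg11 (0.996), Mcoln3 (0.99), Gsto1 (0.90), Cldn10 (0.88), Plxdc1 (0.86), Ano10 (0.80), Spock1 (0.67), Mmp7 (0.59), Nsdhl (0.58) and Sc5d (0.44). Lower were Cst12 (-7.05), Gm4926 (-1.79), Dpp7 (-1.54), Plb1 (-1.10), Fga (-1.03), Camk2b (-1.01), H2-Q4 (-0.91), Zfp950 (-0.90), Gm1673 (-0.83), Pisd-ps1 (-0.65), Prss41 (-0.53), Wfdc10 (-0.41), Spag11a (-0.41), Spink10 (-0.40) and Spint2 (-0.38). The opposite calls of AA465934, Slc16a11, Myh10, Ephb2 and Gm7120 in W/Wv against WT were each lost under some alternatives.

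Among genes below the FPKM filter, which the comparisons do not use, 2 had 3 reads or fewer over the WT libraries and 50 or more over those of a model. Sycp1, a protein of meiotic chromosomes, had 3 reads in WT, 102 in EDL and 0 in W/Wv, and Car6, a secreted carbonic anhydrase, had 0, 61 and 2.

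Cst12 kept 2.73% to 3.36% of its WT level in the 3 EDL libraries and had 8 reads over the 3 W/Wv libraries. Carry-over of WT RNA or of index reads would bring Lcn8 along at 490 FPKM or more, but the highest share of Lcn8 in EDL was 0.0251% of its WT level. A less complete loss in EDL in general was tested too. The other 31 genes that fell 8-fold or more in both models kept a median of 0 percentage points more in EDL than in W/Wv (95% bootstrap interval over genes -0.19 to 0.01). This argues against a difference as large as that of Cst12 within that set only. Genes that fell less in EDL were left out by that choice. Some of the 31, such as Smcp and 9230102K24Rik, had 0 reads in both models. Reads shared with related cystatin genes were not tested and stay open, as does a difference between the models themselves. Ligation stops fluid and sperm of the testis, while the ducts of W/Wv are open and the testis is almost without germ cells.

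WT library 3 lay towards the other groups, with more Lcn5 and Defb15. With gene sets chosen without that library, the shift of genes that rose minus that of genes that fell was 0.36 in log2 (interval 0.31 to 0.45), which restates the pattern and leaves the lower depth of that library open; WT library 1 lay the other way, with shifts of -0.19 and 0.15. A larger share of tissue with the expression of the ligated caput, as a dissection reaching further down the duct could give, was estimated at 11.8% from genes that fell (10.4% to 12.9%) and 10.3% from genes that rose (8.01% to 11.2%). The same estimate gave shares whose intervals lie apart in WT library 1 (-14.4% and -7.29%) and in WT library 2 (4.31% and -2.03%). All these intervals resample genes within 1 library and leave out the spread between libraries. They therefore do not decide whether such a mixture describes the WT libraries as a whole. A weaker testicular signal behind that library would look alike, and no biological explanation was tested.

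Of 41 RNA-binding and splicing genes, a group put together after seeing the calls, 31 rose and 0 fell in EDL against WT. In W/Wv against WT 17 rose and 1 fell. Between the models, 18 of the 41 were lower in W/Wv than in EDL and 0 higher (median log2 difference -0.14). The median stayed below 0 after median-ratio scaling (-0.077, interval -0.11 to -0.058), although that scaling took away part of the difference. After a fit on GC content and transcript length it was -0.15. Because the group was put together from these same calls, a median below 0 was likely in both tests. Neither therefore excludes scaling, GC content or length as a cause. The greater depth of EDL libraries 1 and 3 stays open: the median against EDL library 2 alone was -0.18, but the bound set for this test was wrong, since 1 library gives no spread between libraries. RNA quality and a difference between the models were not tested and stay open too.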

How the results depend on the processing

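The edgeR and DESeq2 fits were added after the data were seen; the other alternatives were planned. The counts of changed genes stayed within 1.5 times of the reported ones in EDL against WT (1158 to 1739) and in W/Wv against WT (1089 to 1622), as did the agreement of EDL and W/Wv effects (1017 to 1477 genes changed alike). The W/Wv against EDL count of 281 was 425 with only the groups compared, and 174 to 385 leaving out 1 library. It was 174 to 207 without 1 of the EDL or W/Wv libraries, and 302 to 385 without 1 of the WT libraries. The WT libraries vary more (chi-square per gene 16.3 to 24.9, against 3.25 to 8.02 in the other groups) and enter the shared spread unless left out. The cause of these shifts was not tested. At 2-fold or more the 12 genes of W/Wv against EDL became 36 (pseudocount 0.1), 41 (edgeR) and 39 (DESeq2), where low genes are not compressed. The lists past the threshold, 4, 6 and 2 in the order of the comparisons, became 1, 1 and 0 with an estimated correlation. For W/Wv against EDL the number was 1 with a pseudocount of 0.1, with a filter at 5 FPKM and with only the groups compared, and 1 to 2 leaving out 1 library; the cause was not tested. Replicate numbers did not pair the libraries (same-number correlations of deviations -0.27 to 0.04), and a replicate block gave 1485, 1380 and 219 genes. Quantile scaling moved the median change of all genes to 0.12 in EDL and 0.11 in W/Wv. Over all named genes and alternatives, 3985 values kept their call, 112 lost it, 41 gained it and 0 reversed. DESeq2 gave no adjusted p for Lcn5, which stays out of these counts. The calls of Erdr1, Spag11a, Spink10, Mmp7 and Prss41 in W/Wv against EDL were lost when some libraries were left out. Genes near 1 FPKM rest on few reads. In the simulations, where most genes were unchanged, changes of the smallest size tried, below 1.5-fold, were often missed with groups of 3. In EDL against WT 1516 of 2013 genes were called, so the simulated share does not carry over to the data. Small changes passed there, such as that of Odf2 (log2 change -0.28, limma adjusted p = 0.00058). How many small changes were missed in the data is not known.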

Other observations

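The tests of the Kit region and the gene groups in this part were chosen after the results were seen; the tests by regrouping libraries were not.

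Of the 449 genes outside the FPKM filter, the 403 with at least 10 reads were tested with edgeR on the recovered reads. Of these, 59 rose and 174 fell in EDL, and 45 rose and 164 fell in W/Wv. The sperm genes Akap4 and Pgk2 had 89 and 55 reads over the WT libraries and 0 over those of both models, at least 32.5-fold and 20.1-fold lower in EDL against a floor of 3 reads. Cd22, a receptor of B cells that passed the filter, had 30 reads in WT, 343 in EDL and 25 in W/Wv, with 99 to 144 in each EDL library. The neutrophil receptor Cxcr2 had 23, 75 and 25 reads, and Il1b had 46, 3 and 19. These genes were picked after their values were seen. Of the fixed markers, 0 of 12 for T and B cells and 1 of 9 for neutrophils, Cxcr2, were in the table. A change of these cell types therefore cannot be read from such single genes.

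Of 46 genes named as zinc-finger proteins, 30 rose and 3 fell in EDL, and 21 rose and 1 fell in W/Wv (median log2 changes 0.27 and 0.18, and 0.22 and 0.13 after median-ratio scaling). Both genes of the inducible heat-shock protein 70 in the table rose in both models. Of 7 Hox genes, 5 rose in EDL, 4 rose and 1 fell in W/Wv, and 4 were lower in W/Wv than in EDL (median log2 changes in that order 0.29, 0.24 and -0.30, after median-ratio scaling 0.12, 0.048 and -0.28, camera p with an estimated correlation 0.21, 0.51 and 0.049).

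In each comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes as reported, 1516 in EDL against WT, 1416 in W/Wv against WT and 281 in W/Wv against EDL. The highest of the other splits gave 0 in each. With 10 splits no share under 0.1 can be reached.

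W/Wv mice may differ from the others in variants linked to Kit (chromosome 5, 75574987 to 75656722), and these were a candidate source of the genes that differ from EDL. Genes within 20 Mb of Kit held 1.78% of the 281 calls, but only 26 genes tested lie there, so that share could not have been large and decides nothing. Of these 26 genes 5 were called, 19.2% against 13.9% elsewhere (Fisher's exact test, two-sided, p = 0.40), and such variants stay open. A difference of strain background over the whole genome cannot be told from genotype here, because the labels give no strain.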
